A study of Rattus norvegicus with 9 samples.

How the data were processed

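RNA sequencing of rat spinal cord was compared between 3 groups of 3 samples each, taken on day 3: sham, injury with saline (SCI_Veh) and injury with α-lipoic acid (SCI_ALA). Groups and replicate numbers came from the sample titles. The authors deposited a table of raw gene counts, whole numbers made with HISAT2 2.0.5 and featureCounts 1.5.0-p3 among the tools that the submitters' processing notes name, on the build Rnor_6.0. The authors also deposited FPKM values for the same genes; each FPKM equals the count divided by gene length and by a library size per sample that was 0.8725 to 1.093 times the sample's total count. The notes name DESeq2 1.20.0 as well, with no role, and state no filter. The table held 36051 genes, 3168 of them named as unannotated, and totals of 13857771 to 15736132 counts per library. No pair of replicates agreed within counting noise (chi-square per degree of freedom 21.0 to 77.1), so none was taken for a repeated deposit of one library. This does not show that replicates came from separate animals.

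Counts were analysed with edgeR 4.0.16 in R 4.3.3, with limma 3.58.1. Genes were filtered with filterByExpr by group (minimum count 10, minimum total 15), which left 16678, and scaled with TMM factors (0.8623 to 1.08). A quasi-likelihood model with group means only and robust estimates (6 residual degrees of freedom, median prior 5.85) was fitted to all 9 libraries. Genes were called at a Benjamini-Hochberg adjusted p below 0.05 with no fold minimum. RLE factors and library totals moved the median of all genes by less than 0.1 on the log2 scale. Folds against a group at 0 counts were bounded with 3 counts over the group. Levels are TMM-scaled counts relative to library size (CPM), with the SD over 3 libraries. Library measures were compared with two-sided exact permutation tests.

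Before the data were examined, 34 gene lists of cell types and pathways, the tests, the rule for named genes and most alternatives were fixed. The lists covered neurons, motor neurons, transmitter receptors, myelin, precursors, astrocytes, microglia, macrophages, neutrophils, lymphocytes, cytokines, inflammasome, complement, interferon, MHC class II, NRF2, antioxidant, NADPH oxidase, ferroptosis, lipoic acid, respiratory chain, glycolysis, cholesterol, apoptosis, stress response, cell cycle, matrix, endothelium, immediate-early genes, erythroid cells, muscle and Schwann cells. Of their 454 genes, 437 were in the table, 2 of them under another symbol, and 417 were tested. Lists were tested with camera (preset correlation 0.01, adjusted over the 34 lists), with camera at a correlation estimated per list, and with fry. The named genes were the 10 rising and 10 falling genes with the largest change that passed, had a mean of at least 50 counts and did not overlap between groups (3 each way for SCI_ALA against sham), 30 fixed genes whatever their result, up to 4 members per list with the smallest p, and the 10 genes moved back with the smallest p. Some of the named genes are not reported here.

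Genes moved back were those that passed in SCI_Veh against sham and, with the opposite sign, in SCI_ALA against SCI_Veh. Because both comparisons share the SCI_Veh libraries, 50 simulations with SCI_ALA unchanged from SCI_Veh gave the values that sharing alone produces, and all 20 arrangements of the 6 injured libraries were computed. The other splits of the libraries into groups of the same sizes were counted, 10 for each pair of groups and 100 drawn of 280 for the 3 groups.

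The procedure was tested on simulated data with known changes. Changes were placed in 67 genes at 1.5-fold, 67 at 2-fold and 66 at 4-fold. Of these, 5.97%, 23.9% and 69.7% were recovered in SCI_Veh against sham, and 4.48%, 31.3% and 80.3% in SCI_ALA against SCI_Veh. In SCI_ALA against sham the shares were 4.48%, 28.4% and 75.8%. Where so few genes change, most 1.5-fold and 2-fold changes and some 4-fold changes go undetected at this depth and number of libraries. The adjusted threshold is less strict where many genes change. The shares may therefore be too low for the comparisons with sham, where 38% and 33.1% of genes passed. False calls were 4 of 70, 7 of 84 and 4 of 76.

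Alternatives were RLE factors, library totals only, mitochondrial and hemoglobin genes left out, no count filter, at least 50 counts in 3 libraries, a minimum log2 fold change of 1, a replicate block, robust=FALSE, only the 2 groups compared, each library left out, DESeq2 1.42.0, and limma with an intensity trend on log2 FPKM with a pseudocount of 1 (at least 1 FPKM in 3 libraries, or all genes) or 0.1. Removal of each library's trend with gene length (loess, span 0.5) and leaving out sham 2 and SCI_ALA 3 together were added after seeing the data. A correction for GC content was not made because no sequence of the authors' build was at hand, and genes absent from the table were left out. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.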

Results

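Spinal cord RNA was compared on day 3 after a thoracic contusion among sham rats, injured rats given saline (SCI_Veh) and injured rats given α-lipoic acid (SCI_ALA), with 3 libraries per group. α-Lipoic acid is a dithiol cofactor of mitochondrial dehydrogenases and is given as an antioxidant. The first principal component carried 53.2% of the variance and placed sham libraries between 81.8 and 102 and injured libraries between -62.6 and -30.1. Mitochondrially encoded genes took 12.2 ± 3.54% of counts in sham, 7.35 ± 0.804% in SCI_Veh and 7.50 ± 0.949% in SCI_ALA (mean ± SD, n = 3). Each injured group differed from sham with a two-sided exact permutation p of 0.1, the smallest that 3 against 3 libraries allow. Hemoglobin genes took 0.0966 ± 0.0722%, 0.0868 ± 0.0589% and 0.173 ± 0.0907% (SCI_ALA against SCI_Veh, exact permutation p = 0.2). Libraries also differed in how far long genes were favoured. For genes with a mean log2 CPM above 3, each library's deviation from the mean of all 9 libraries was correlated with gene length across genes (Spearman). The correlation ran from -0.188 (sham 2) to 0.342 in sham, 0.0517 to 0.118 in SCI_Veh and -0.46 (SCI_ALA 3) to 0.0328 in SCI_ALA. SCI_ALA libraries thus all lay below SCI_Veh (means -0.237 and 0.075, exact permutation p = 0.1), and this measure is confounded with treatment. The correlations compare libraries with one another and are not correlations of the level itself with length. The labels do not say whether replicates came from separate animals. The p-values therefore measure the spread between these samples, which may be technical.

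Injury with saline raised genes of phagocytic macrophages and of dividing cells, and lowered genes of neurons, myelin, resting astrocytes and cholesterol synthesis. With an estimated correlation the presynaptic, neurotransmitter, myelin, homeostatic astrocyte and cholesterol synthesis lists lost their call (adjusted p = 0.21, 0.21, 0.277, 0.0842 and 0.129), while the phagocytic macrophage and cell cycle lists kept it (0.014 each). Gpnmb, a glycoprotein of phagocytes, was 87.9-fold higher in SCI_Veh than in sham (log2 6.46, SE 0.26, n = 3 each, edgeR adjusted p = 1.05e-07). It stood at 2620 ± 268 against 29.8 ± 6.23 CPM and lies on chromosome 4, 78694447 to 78715683 (ENSRNOG00000008816, build Rnor_6.0 per the submitters' processing notes). Hmox1, heme oxygenase 1, was 76.7-fold higher (log2 6.26, SE 0.25), and Spp1, which encodes osteopontin, 69.8-fold (log2 6.13, SE 0.36). Mmp12, macrophage elastase, was 352-fold higher (log2 8.46, SE 0.60). Cd8a, 99.7-fold higher (log2 6.64, SE 0.73), and Cd8b, 112-fold, encode CD8, which in rats is carried by macrophages as well as T cells. Serpina3n, a protease inhibitor of reactive astrocytes, had no counts in sham and was at least 853-fold higher, against a floor of 3 counts over the group. Sprr1a, induced in injured axons, was at least 76-fold higher. The steepest falls included Slc25a18, a mitochondrial glutamate carrier (16.2-fold lower, log2 -4.02, SE 0.25), Slc7a10, an amino acid transporter of astrocytes (14-fold lower), and Slc6a11, a GABA transporter (9.66-fold lower).

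In the neuronal cytoskeleton and presynaptic list, 11 of 15 tested genes fell and 1 rose (13 and 1 adjusted over the list alone, median log2 -1.32). Snap25, a SNARE protein of transmitter release, was 4.48-fold lower (log2 -2.16, SE 0.27), Syt1 3.94-fold and Rbfox3, a nuclear marker of neurons, 3.96-fold. The riser, chosen after its values were seen, was Gap43, a growth cone protein (log2 0.98, SE 0.23). Of 15 neurotransmitter receptors and transporters, 14 fell (14 adjusted over the list alone, median -1.66). Gria4, an AMPA receptor subunit, was 4.50-fold lower. The myelin and mature oligodendrocyte list had 11 of 14 members lower (11 adjusted over the list alone, median -1.30), with Mbp 2.27-fold lower. Homeostatic astrocyte genes fell in 13 of 14 and rose in 1 (13 and 1 adjusted over the list alone, median -1.82), and Aqp4, the aquaporin of astrocyte endfeet, was 5.93-fold lower. Camera called these 4 lists at adjusted p 1.7e-06, 6.21e-09, 2.25e-06 and 1.45e-10. With an estimated correlation they had adjusted p = 0.21, 0.21, 0.277 and 0.0842 (lowest over the alternatives 6.61e-09, 2.83e-12, 1.97e-09 and 6.85e-15). Reactive astrocyte genes rose in 12 of 15 (13 adjusted over the list alone, median 2.05, the same with Serpina3n at its bound). This list had a camera adjusted p of 3.51e-13, and 0.00657 with an estimated correlation. Timp1 was 13.3-fold, Cd44 4.96-fold and Vim 4.09-fold higher, while Gfap, the astrocyte filament gene, did not pass (log2 0.06, SE 0.23, adjusted p = 0.85).

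Oligodendrocyte precursor markers had 1 gene of 9 higher, Vcan (6.32-fold), and 1 lower, Bcan (3.19-fold), both chondroitin sulfate proteoglycans (1 and 1 adjusted over the list alone, median 0.20, adjusted p = 0.459). Motor neuron markers had 3 of 7 lower and 1 higher, the same counts adjusted over the list alone (median -0.29, adjusted p = 0.221). Chat, of acetylcholine synthesis, was 2.65-fold and Chodl 4.33-fold lower. Schwann cell markers had 5 of 9 lower and 1 higher (6 and 1 adjusted over the list alone, median -1.06, adjusted p = 0.0706). That p was 0.0248 without SCI_Veh 2 and 0.0238 without sham 3, with a range over alternatives of 0.0238 to 0.42. Endothelial and barrier genes had 1 higher and 3 lower of 10, the same adjusted over the list alone (median 0.26, adjusted p = 0.985). Skeletal muscle markers had 1 lower of 9 and 0 adjusted over the list alone by edgeR, with 1 at an unadjusted p and 1 by DESeq2 (median -0.22, adjusted p = 0.642). By edgeR, 0 of 8 erythroid cell markers passed and 0 adjusted over the list alone, with 0 at an unadjusted p and 0 by DESeq2 (median -0.60, adjusted p = 0.488).

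Phagocytic macrophage and activated microglia genes rose in 16 of 17 (16 adjusted over the list alone, median 3.00). Their camera adjusted p was 4.25e-37, and 0.014 with an estimated correlation. Lgals3, galectin 3, was 15.1-fold, Cd68, a lysosomal glycoprotein, 12.4-fold and Itgax 10.8-fold higher. All 7 alternatively activated macrophage genes rose (7 adjusted over the list alone, median 1.84), with Arg1, arginase 1, 4.10-fold higher. Homeostatic microglia markers rose in 6 of 10 (6 adjusted over the list alone, median 0.86), with Csf1r 2.78-fold and P2ry12 2.06-fold higher. Cytokines and chemokines rose in 12 of 15 (12 adjusted over the list alone, median 2.62), and Ccl3 was 20.9-fold and Ccl2 18-fold higher. Inflammasome and pyroptosis genes rose in 10 of 11 (10 adjusted over the list alone, median 1.15), with Tlr2 5.17-fold and Nlrp3 2.97-fold higher. NADPH oxidase and oxidant-producing genes rose in 6 of 10 (6 adjusted over the list alone, median 1.91), with the oxidase subunits Ncf1 5.98-fold and Cybb 3.49-fold higher. Complement genes rose in 6 and fell in 1 of 12, the same counts adjusted over the list alone (median 1.25), with the receptor gene C3ar1 7.18-fold higher. Camera called these 6 lists at 1.36e-05, 0.0059, 4.27e-05, 2.6e-05, 2.13e-05 and 4.81e-05. With an estimated correlation they had adjusted p = 0.177, 0.212, 0.212, 0.21, 0.179 and 0.283 (lowest over the alternatives 6.53e-07, 0.000274, 6.05e-07, 3.88e-07, 9.58e-07 and 3.88e-07).

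Interferon-stimulated genes went the other way, with 9 of 13 lower (9 adjusted over the list alone, median -1.62). Oas1a was 3.07-fold lower. The list had an adjusted p of 0.00193, and adjusted p = 0.42 with an estimated correlation (lowest over the alternatives 2.47e-06). Its mean log2 levels were 5.91 to 7.68 in the sham libraries and 4.84 to 5.46 in SCI_Veh. By edgeR, 0 of 8 MHC class II genes passed and 0 adjusted over the list alone, with 0 at an unadjusted p and 0 by DESeq2 (median -0.58, adjusted p = 0.772). Lymphocyte markers rose in 2 of 9 (2 adjusted over the list alone, median 1.2, adjusted p = 0.157), Cd8a being 1 of them. Neutrophil markers had 1 riser of 10, Csf3r (4.27-fold, 1 adjusted over the list alone), against a list median of -1.34 (adjusted p = 0.78). Neutrophil list levels were 2.28 to 5.08 in sham and 2.16 to 3.97 in SCI_Veh.

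Cell cycle genes rose in all 16 tested members (16 adjusted over the list alone, median 3.42, camera adjusted p = 5.72e-36, and 0.014 with an estimated correlation). Rrm2, a ribonucleotide reductase subunit, was 25.7-fold and Mki67, a proliferation marker, 9.97-fold higher. Apoptosis and p53 target genes rose in 11 of 12 (11 adjusted over the list alone, median 1.19, adjusted p = 9.78e-06, and 0.0474 with an estimated correlation). Cdkn1a was 2.37-fold higher. All 16 cholesterol synthesis genes fell (16 adjusted over the list alone, median -1.70), with Hmgcs1 7.27-fold lower (log2 -2.86, SE 0.23). Their adjusted p was 7.84e-18, and adjusted p = 0.129 with an estimated correlation (lowest over the alternatives 2.56e-24). Immediate-early genes rose in 6 of 10 (6 adjusted over the list alone, median 1.25), with Egr1 2.90-fold higher. Integrated stress response genes rose in 5 of 10 (5 adjusted over the list alone, median 0.41), with Atf3 9.79-fold higher. Glycolysis and hypoxia genes had 6 higher and 1 lower of 15 (7 and 1 adjusted over the list alone, median 0.39), with Ldha, lactate dehydrogenase, 4.21-fold higher. These 3 lists were called at adjusted p 0.00449, 0.015 and 0.00879. With an estimated correlation they had adjusted p = 0.21, 0.21 and 0.316 (lowest over the alternatives 0.000931, 0.00059 and 0.00117). Extracellular matrix genes rose in 7 of 16 (7 adjusted over the list alone, median 0.80, adjusted p = 0.0104), with Postn, periostin, 16-fold higher. That p was 0.0705 without sham 2, and adjusted p = 0.421 with an estimated correlation (lowest over the alternatives 0.000519).

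Among redox genes, NRF2 targets rose in 6 and fell in 1 of 16 (7 and 1 adjusted over the list alone, median 0.58). They had an adjusted p of 0.00417, and adjusted p = 0.21 with an estimated correlation (lowest over the alternatives 0.00033). Hmox1 led them, while Txnrd1, thioredoxin reductase 1, was 1.50-fold higher and Me1, malic enzyme, 2.17-fold lower. Gclm, of glutathione synthesis, and Slc7a11, of cystine import, did not pass (log2 0.09 and -0.51, SE 0.13 and 0.28, adjusted p 0.627 and 0.177). Nqo1, a quinone reductase, had a log2 change of 0.42 (SE 0.19, adjusted p = 0.101). That p was 0.0166 without sham 2, with a range over alternatives of 0.0129 to 0.234. Antioxidant enzymes had 3 risers of 15 (3 adjusted over the list alone, median 0.11, adjusted p = 0.374), namely Gpx1 (3.20-fold), Prdx5 (2.06-fold) and Prdx4 (1.73-fold). Sod1, Sod2 and Cat had log2 changes of 0.11, 0.09 and 0.13 (adjusted p 0.667, 0.834 and 0.493).

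Ferroptosis and iron handling genes rose in 6 of 14 (6 higher and 1 lower adjusted over the list alone, median 0.36), with Ftl1, ferritin light chain, 6.45-fold higher. The list's adjusted p of 0.0572 was 0.0472, 0.0366, 0.0416, 0.0384 and 0.0371 without SCI_Veh 1, SCI_Veh 3, sham 3, SCI_ALA 1 and SCI_ALA 3 (range over alternatives 0.00159 to 0.316). Of the 14 genes that make or use lipoic acid, 7 fell and 1 rose, the same counts adjusted over the list alone (median -0.45). Pdhb, a pyruvate dehydrogenase subunit, was 1.79-fold and Bckdha, of branched-chain keto acid oxidation, 1.82-fold lower. This list had an adjusted p of 0.0764, and 0.0374 without sham 3 (range over alternatives 0.00474 to 0.316). Dld, the lipoamide dehydrogenase, was 1.44-fold lower (adjusted p = 0.0217), with 0.0596, 0.0709, 0.0508 and 0.0506 without SCI_Veh 1, 2, 3 and sham 2 (range 0.00581 to 0.0709). Respiratory chain genes fell in 5 of 19 (2 adjusted over the list alone, median -0.42), with Sdha 1.76-fold lower. Their adjusted p of 0.0468 was 0.0629, 0.0515, 0.0526, 0.381 and 0.0525 without SCI_Veh 1, 2 and 3, sham 2 and SCI_ALA 2. They had adjusted p = 0.708 with an estimated correlation (lowest over the alternatives 0.00632).

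Of 16678 genes tested, 6337 differed between SCI_Veh and sham at an adjusted p below 0.05 by the edgeR quasi-likelihood test, 3248 higher and 3089 lower, and 3801 of them by at least 2-fold. Camera called 22 of 34 lists, 15 higher and 7 lower. With an estimated correlation 4 remained, the reactive astrocyte, phagocytic macrophage, apoptosis and cell cycle lists. The cytokine gene Il6 was 6.29-fold higher (adjusted p = 0.0343), with 0.0516, 0.0558, 0.104, 0.065 and 0.0694 without SCI_Veh 1, 2, 3, sham 1 and sham 2 (range 0.00835 to 0.104). Col1a1, a collagen gene, was 1.91-fold higher (adjusted p = 0.0283), with 0.155, 0.0657 and 0.0999 without SCI_Veh 2, sham 1 and sham 2 (range 0.00698 to 0.155). Il1b had a log2 change of 2.21 (SE 0.99, adjusted p = 0.112), with 0.0424 without SCI_ALA 1 and 0.0258 without SCI_ALA 2 (range 0.0202 to 0.319). Tnf and Gpx4 had too few counts to test (2 and 29 over all libraries), and Itgam and Nos2 were not analysed here. Fth1, Slc40a1 and Cldn5 had 0 counts in every library. The ferroptosis list was thus tested without Gpx4, Fth1 and Slc40a1, and the endothelial list without Cldn5. Whether counts this low reflect low expression was not tested.

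**Figure D1:**
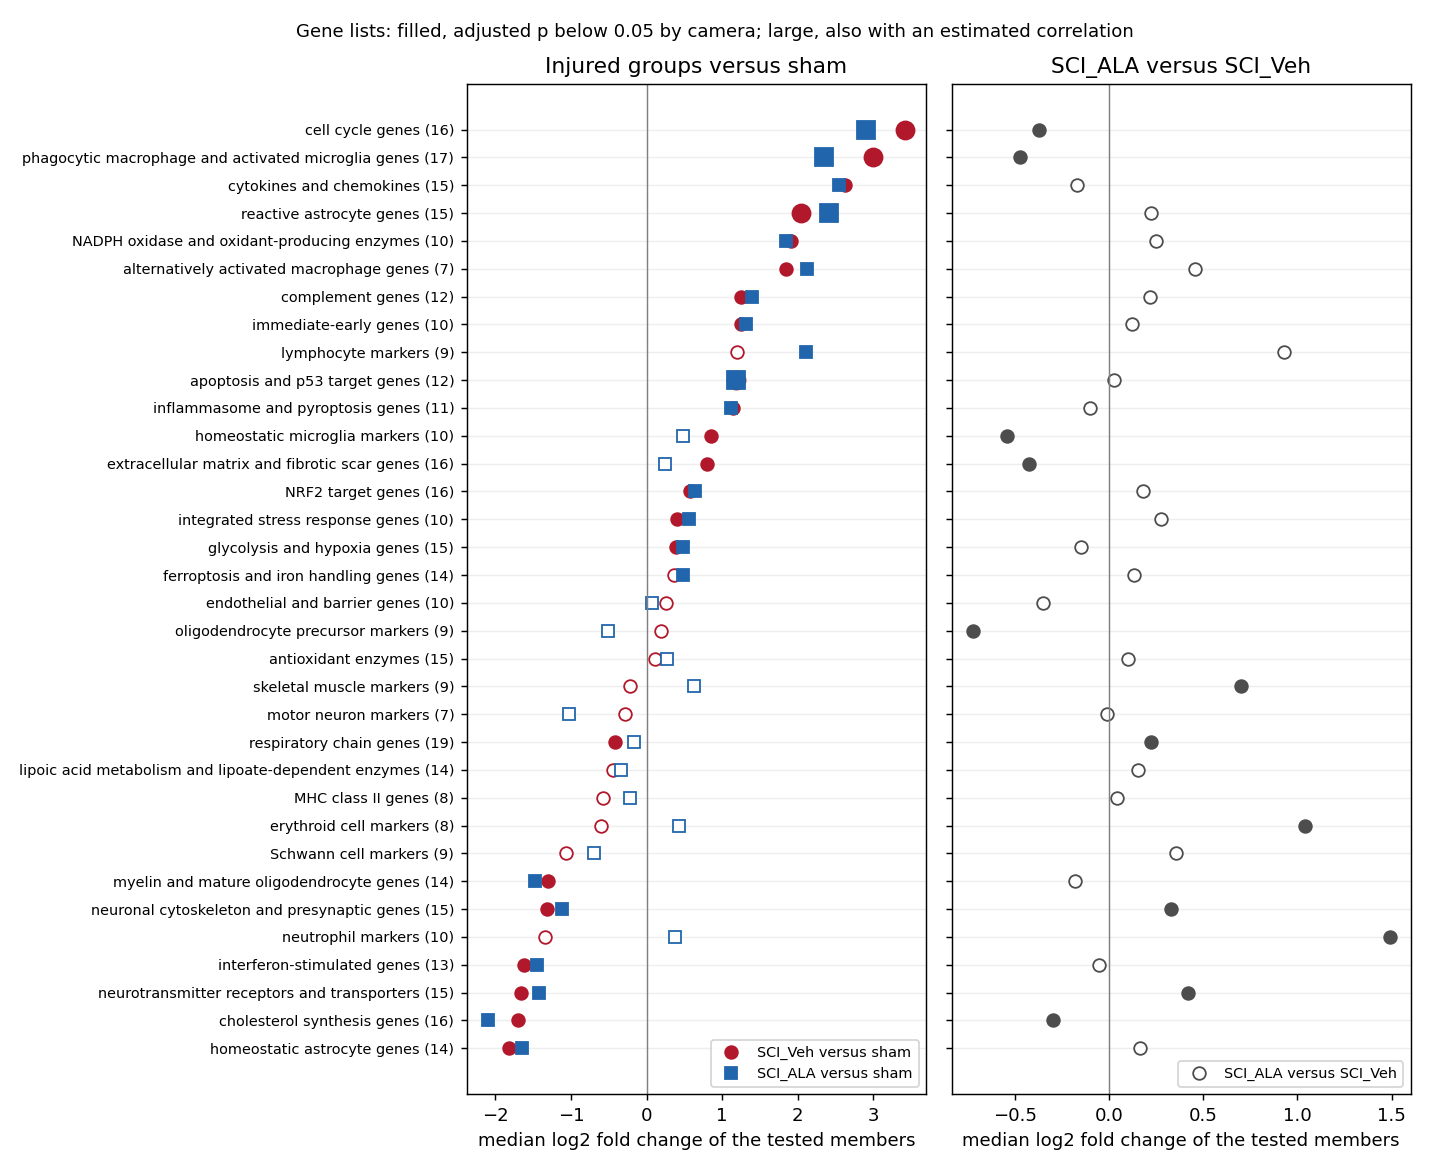
Median log2 fold change of the tested members (horizontal axes) of 34 gene lists, number tested in brackets, for SCI_Veh and SCI_ALA against sham (left) and SCI_ALA against SCI_Veh (right). Filled symbols mark an adjusted p below 0.05 by camera, and large symbols the 4 lists per comparison with sham that also passed with an estimated correlation, which none did on the right.

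Between the injured groups few genes passed. Ptprz1, a receptor phosphatase and proteoglycan of glial precursors, was 2.75-fold lower in SCI_ALA than in SCI_Veh (log2 -1.46, SE 0.20, 41.3 ± 4.26 against 114 ± 6.17 CPM, sham 87.6, n = 3 each). It lies on chromosome 4, 49941304 to 50140762 (ENSRNOG00000006030). Tgfbr1, a TGF-β receptor (ENSRNOG00000007036, chromosome 5, 63050758 to 63119635), was 2.38-fold lower (log2 -1.25, SE 0.18). Vcan, which encodes versican (ENSRNOG00000029212, chromosome 2, 18490102 to 18565842), was 2.31-fold lower (log2 -1.21, SE 0.19). Sccpdh was 14.4-fold higher (log2 3.85, SE 0.55), and Etnppl, a phosphoethanolamine lyase of astrocytes, 6.71-fold (log2 2.75, SE 0.43). Fmo1, a flavin monooxygenase (2.96-fold), Sult1d1 and Sult1a1, sulfotransferases (2.63-fold and 2.61-fold), and Ass1, of arginine synthesis (2.29-fold), were also higher. So was Pvalb, a calcium-binding protein of interneurons (2.32-fold), while Mmp15, Slc37a2 and Afap1l2 were 2.92-fold, 2.77-fold and 2.25-fold lower. Rplp2 was 5.68-fold lower (adjusted p = 0.0181) and Rps27a of chromosome 14 was 3.23-fold higher. Both encode ribosomal proteins with near-identical gene copies, so which copy changed is uncertain. The summed copies changed by log2 0.07 for Rplp2 and 0.55 for Rps27a (adjusted p 0.943 and 0.459).

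By edgeR, 20 genes passed, 13 higher and 7 lower, all but Rplp2 at an adjusted p of 0.0483. An unadjusted p below 0.05 was found for 2050 genes, against 833.9 expected by chance, and DESeq2 called 416, all 20 among them. The log2 changes of this comparison had a Spearman correlation of -0.277 with gene length over all tested genes. Because SCI_ALA libraries favoured short genes, the excess of small p cannot be credited to treatment alone. With the length trend of each library removed, 18 genes passed by edgeR. Other choices ended most calls, with 1 gene left under library totals only, 1 with robust=FALSE and 0 with a replicate block (edgeR, 2096 unadjusted), and limma on FPKM called 3, 0 and 1 (2030, 1945 and 2504 unadjusted). The count was 3, 4 and 1 without SCI_Veh 1, 2 and 3, 11, 86 and 3 without sham 1, 2 and 3, and 2, 0 and 2 without SCI_ALA 1, 2 and 3 (edgeR, 1325 unadjusted without SCI_ALA 2). No gene of this comparison therefore passed in every such fit.

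Camera called 6 lists lower in SCI_ALA, those of precursor cells, microglia, macrophages, dividing cells, cholesterol synthesis and extracellular matrix, and 0 with an estimated correlation. Oligodendrocyte precursor markers had log2 changes below 0 in 8 of 9 tested members, with 2 passing over all genes (Ptprz1 and Vcan) and 6 adjusted over the list alone (median -0.73, camera adjusted p = 6.23e-10). They had adjusted p = 0.166 with an estimated correlation (lowest over the alternatives 7.17e-13). Homeostatic microglia markers had log2 changes below 0 in all 10 (median -0.54, adjusted p = 9.15e-07), with 0 passing over all genes by edgeR, 5 adjusted over the list alone, 5 at an unadjusted p and 4 by DESeq2. Here adjusted p = 0.186 with an estimated correlation (lowest over the alternatives 2.76e-11). Tmem119 and Cx3cr1, both microglial surface proteins, had log2 changes of -0.98 and -0.96 (adjusted p 0.16 and 0.198). Phagocytic macrophage genes had log2 changes below 0 in 16 of 17 (median -0.48, adjusted p = 4.93e-09), with 0 passing over all genes by edgeR, 5 adjusted over the list alone, 8 at an unadjusted p and 5 by DESeq2. This list had adjusted p = 0.231 with an estimated correlation (lowest over the alternatives 2.91e-14).

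Spp1 had a log2 change of -1.78 (SE 0.30, 3349 against 11470 CPM, adjusted p = 0.0527), with 0.0286 without sham 1 and 0.0328 without sham 2 (range 5.32e-07 to 0.184). Gpnmb had -0.98 (SE 0.20, adjusted p = 0.108), with 0.0386 without sham 2 (range 0.000396 to 0.399). Mean log2 levels of the macrophage list were 8.26 to 8.75 in the SCI_ALA libraries and 8.94 to 9.13 in SCI_Veh. Those of the reactive astrocyte list were 7.19 to 7.54 and 7.07 to 7.26. Cell cycle genes had log2 changes below 0 in 15 of 16 (median -0.38, adjusted p = 6.41e-05), with 0 passing over all genes and 0 adjusted over the list alone by edgeR, 4 at an unadjusted p and 0 by DESeq2. Their adjusted p = 0.64 with an estimated correlation (lowest over the alternatives 1.82e-08), and Mki67 had a log2 change of -0.83 (adjusted p = 0.535).

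**Figure D2:**
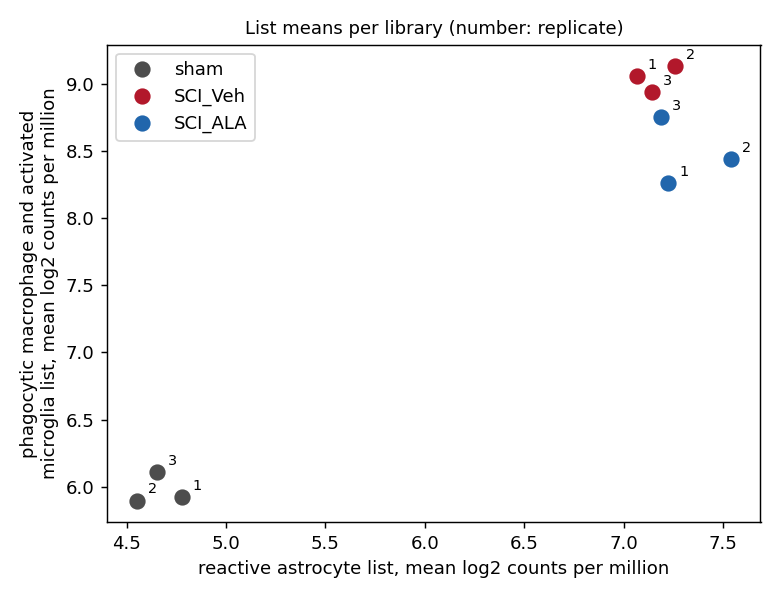
Mean log2 CPM of the phagocytic macrophage and activated microglia list (vertical axis) against that of the reactive astrocyte list (horizontal axis), 1 point per library with its replicate number. SCI_ALA libraries lie between 8.26 and 8.75 on the vertical axis and SCI_Veh libraries between 8.94 and 9.13, at astrocyte levels of 7.07 to 7.54.

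Cholesterol synthesis genes again had log2 changes below 0, in 14 of 16 members (median -0.30, adjusted p = 0.00326). By edgeR 0 passed over all genes and 0 adjusted over the list alone, with 5 lower and 1 higher at an unadjusted p and 0 by DESeq2. They had adjusted p = 0.649 with an estimated correlation (lowest over the alternatives 4.25e-05). The extracellular matrix list had a median of -0.43 over 16 genes (1 lower adjusted over the list alone, adjusted p = 0.0361). That p was 0.701, 0.122 and 0.102 without SCI_Veh 2, SCI_ALA 1 and SCI_ALA 3 and 0.0652 with library totals only, and adjusted p = 0.649 with an estimated correlation (range 0.00103 to 0.701). Postn and Col1a1 had log2 changes of -1.37 and -0.73 (adjusted p 0.177 and 0.355). Neuronal cytoskeleton and presynaptic genes had log2 changes above 0 in 13 of 15 (median 0.33, adjusted p = 0.000486), with 0 passing over all genes by edgeR, 1 adjusted over the list alone, 5 at an unadjusted p and 1 by DESeq2. This list had adjusted p = 0.649 with an estimated correlation (lowest over the alternatives 2.25e-07). Neurotransmitter receptors and transporters had log2 changes above 0 in 12 of 15 (median 0.42, adjusted p = 0.0039), with 0 passing over all genes and 0 adjusted over the list alone by edgeR, 5 at an unadjusted p and 0 by DESeq2. That p was 0.126 without SCI_Veh 2 and 0.0574 without SCI_ALA 1, and adjusted p = 0.649 with an estimated correlation (lowest over the alternatives 2.37e-06). Vamp1 and Snap25 had log2 changes of 0.82 and 0.84 (adjusted p 0.167 and 0.237).

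Camera also called the neutrophil, erythroid, skeletal muscle and respiratory chain lists higher in SCI_ALA. Medians were 1.49 over 10 neutrophil markers, 1.04 over 8 erythroid cell markers, 0.70 over 9 skeletal muscle markers and 0.22 over 19 respiratory chain genes, each at a camera adjusted p of 0.0206. Each had adjusted p = 0.649 with an estimated correlation (lowest over the alternatives 9.19e-05, 1.28e-06, 0.00065 and 0.00182). Over all genes 0 members of these 4 lists passed by edgeR, and adjusted over the list alone 1 muscle gene did. At an unadjusted p the counts were 0, 0, 1 and 0, the same as by DESeq2. S100a8, a neutrophil calcium-binding protein, and Hba-a1, an alpha globin, had log2 changes of 2.04 and 1.08 (adjusted p 0.469 and 0.545). The neutrophil call ended without SCI_Veh 1, SCI_Veh 2 and SCI_ALA 3 (0.0579, 0.126 and 0.162), and so did the erythroid call (0.103, 0.0998 and 0.162). The erythroid call also ended with mitochondrial and hemoglobin genes left out (0.217). That choice takes the globin genes out of the erythroid list itself, so this loss is no separate sign of an unstable call. The muscle call ended without SCI_Veh 2 and SCI_ALA 2 (0.214 and 0.416), and the respiratory chain call without SCI_ALA 2 and SCI_ALA 3 (0.0597 and 0.162). With the length trend of each library removed, a choice made after seeing the data, the medians were 1.24, 0.87, 0.62 and 0.15 and adjusted p 0.0583, 0.0598, 0.0513 and 0.197. Mean log2 levels of the neutrophil list ran from 2.89 to 4.89 in SCI_ALA and 2.16 to 3.97 in SCI_Veh, and those of the erythroid list from 4.07 to 5.76 and 3.15 to 5.04.

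The lists closest to oxidant defence did not pass, and by edgeR 0 of their members passed over all genes. NRF2 targets had a median of 0.18 over 16 genes (adjusted p = 0.0783, and 0.0222 without SCI_ALA 1, range 0.0222 to 0.649). Of these, 2 were higher adjusted over the list alone and 2 by DESeq2, with 3 higher and 2 lower at an unadjusted p. Nqo1 had a log2 change of 0.86 (SE 0.19, 143 ± 19.4 against 78.8 CPM, adjusted p = 0.116), with 0.0397 without sham 2 (range 0.00303 to 0.344). Gsta4, a glutathione transferase, had 0.98 (adjusted p = 0.101), with 0.0412 without sham 2 (range 0.00172 to 0.376), and Hmox1 had -0.23 (adjusted p = 0.671). Gclm, Slc7a11 and Txnrd1 had log2 changes of 0.22, 0.18 and 0.16 (adjusted p 0.522, 0.835 and 0.677). Antioxidant enzymes had a median of 0.10 over 15, which was -0.05 with the length trend removed (adjusted p = 0.114, and 0.00305 without SCI_ALA 1, range 0.00305 to 0.649). Of these, 0 passed adjusted over the list alone by edgeR and 0 by DESeq2, with 3 higher and 1 lower at an unadjusted p. Sod1, Sod2, Cat and Gpx1 had log2 changes of 0.37, 0.60, -0.37 and 0.09 (adjusted p 0.438, 0.451, 0.312 and 0.915). NADPH oxidase and oxidant-producing genes had a median of 0.25 over 10 (1 adjusted over the list alone, adjusted p = 0.497), with Cybb at -0.34. Ferroptosis and iron handling genes had 0.13 over 14 (1 higher and 2 lower adjusted over the list alone, adjusted p = 0.931). Genes that make or use lipoic acid had 0.15 over 14 (adjusted p = 0.315), with 0 adjusted over the list alone by edgeR, 2 at an unadjusted p, 0 by DESeq2 and Dld at 0.13.

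The other lists also stayed short of the threshold between the injured groups. Reactive astrocyte genes had a median of 0.22 over 15 (1 lower adjusted over the list alone, adjusted p = 0.194). That p was 0.0216 with only the 2 groups compared and 0.0449 without both sham 2 and SCI_ALA 3 (range 0.0216 to 0.655). Gfap, Vim and Lcn2 had log2 changes of 0.38, 0.10 and 1.34 (adjusted p 0.525, 0.879 and 0.23, the last 0.0316 without sham 2, range 0.00656 to 0.539). Homeostatic astrocyte genes had a median of 0.17 (adjusted p = 0.194), with 0.0119 without SCI_Veh 1 and 0.0318 without SCI_ALA 3 (range 0.0119 to 0.649). Alternatively activated macrophage genes had 0.46 (adjusted p = 0.0783), with 0.000723, 0.0257 and 0.0383 without SCI_Veh 2, sham 3 and SCI_ALA 1 (range 0.000723 to 0.649). Myelin genes had -0.18 (adjusted p = 0.358), with 0.000723 without SCI_Veh 2 (range 0.000723 to 0.86). Integrated stress response genes had 0.28 (adjusted p = 0.0627), with 0.0364 and 0.0272 without SCI_ALA 1 and 2 (range 0.0272 to 0.649). Endothelial genes had -0.35 (adjusted p = 0.126), with 0.0337 without SCI_Veh 3 and 0.0364 without SCI_ALA 1 (range 0.0337 to 0.649). Inflammasome genes had -0.10 (adjusted p = 0.213), with 0.0211 without SCI_ALA 3 (range 0.0211 to 0.914). Interferon-stimulated genes had -0.06 (adjusted p = 0.497), with 0.00297 without SCI_ALA 3 (range 0.00144 to 0.96). Cytokines and chemokines had -0.17 with a mean of 0.06, and the test pointed down (adjusted p = 0.739, and 0.0272 without SCI_ALA 2, range 0.0272 to 0.985).

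Of the remaining lists, lymphocyte markers had a median of 0.93 (adjusted p = 0.0783), complement genes 0.22 (0.497), glycolysis and hypoxia genes -0.15 (0.251), immediate-early genes 0.12 (0.333) and Schwann cell markers 0.36 (0.251). MHC class II genes had 0.04 with a mean of -0.15 and the test pointing up (adjusted p = 0.881), and motor neuron markers -0.01 with a mean of 0.05 (0.727). Apoptosis genes had 0.03, but -0.03 with library totals only (0.472). Adjusted over the list alone, 1 gene passed in each of the cytokine, stress response, reactive astrocyte and Schwann lists and 2 in the glycolysis list. Those of these and the preceding 9 lists without any edgeR call by either adjustment had at most 2 genes either way at an unadjusted p and at most 1 by DESeq2. The fixed genes Mbp, Rbfox3, Chat, P2ry12 and Cd68 had log2 changes of 0.36, 0.54, 0.16, -0.54 and -0.50 (adjusted p 0.65, 0.596, 0.893, 0.313 and 0.424). Il1b, Il6, Ccl2 and Nlrp3 had 0.33, 0.32, -0.19 and -0.45 (adjusted p 0.917, 0.901, 0.861 and 0.59).

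Of the 20 genes that passed between the injured groups, 15 had changed with injury in the opposite direction. Among them, 10 genes lowered by injury were higher in SCI_ALA and 5 raised by injury were lower. The other 5 had not passed between SCI_Veh and sham. Tgfbr1 rose 5.67-fold with injury and stood at 41.9, 238 and 100 CPM in sham, SCI_Veh and SCI_ALA, and Vcan at 30.2, 191 and 82.8. Ass1 and Afap1l2 had log2 differences from sham of -0.05 and 0.09 in SCI_ALA (adjusted p 0.86 and 0.732), and Sccpdh of 0.37 (adjusted p = 0.579). Pvalb, Cabp1, a neuronal calcium sensor, and Carmil2 stayed lower than sham (log2 -0.66, -0.44 and -0.52, adjusted p 0.0211, 0.0374 and 0.0181). Independent lists would share 2.408 and 1.363 genes in these directions. Both comparisons use the same SCI_Veh libraries, and part of the excess may come from the shared controls. Over all tested genes the log2 changes had a covariance of -0.246, against -0.103 on average in 50 simulations with SCI_ALA unchanged from SCI_Veh, and 63.6% had opposite signs against 55.9%. The simulations drew each gene independently, so they lack any correlation between genes that real libraries hold. The count of 15 was 3, 1 and 1 without SCI_Veh 1, 2 and 3, 7, 51 and 2 without sham 1, 2 and 3, and 1, 0 and 2 without SCI_ALA 1, 2 and 3 (edgeR), and DESeq2 gave 255.

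**Figure D3:**
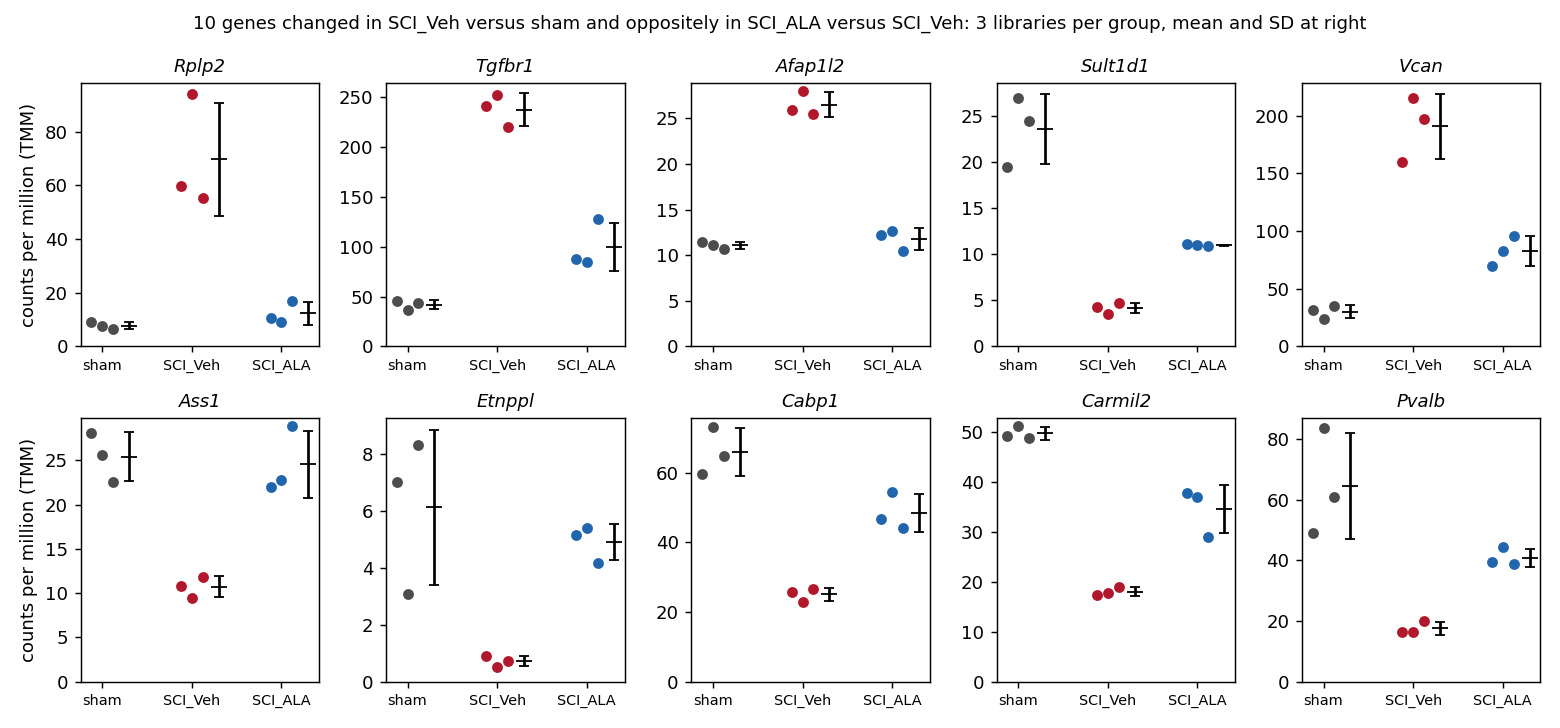
TMM-scaled CPM (vertical axes, starting at 0) of 10 genes that changed between SCI_Veh and sham and oppositely between SCI_ALA and SCI_Veh, 1 point per library, with the mean and SD of each group of 3 at its right. Rplp2 has near-identical copies, so which copy changed is uncertain, and Tgfbr1 stood at 41.9, 238 and 100 in sham, SCI_Veh and SCI_ALA.

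Cord from treated injured rats remained far from sham. Hmox1 was 65.4-fold higher in SCI_ALA than in sham (log2 6.03, SE 0.25, n = 3 each), Ccl2 15.7-fold, Cd68 8.80-fold, Mki67 5.59-fold and Vim 4.39-fold. Gpx1, a glutathione peroxidase, was 3.42-fold higher. Serpina3n was at least 931-fold and Ucn2, a peptide of the corticotropin-releasing factor family, at least 107-fold higher. Slc25a18 was 20.1-fold, Slc7a10 12.6-fold and Scd, a fatty acid desaturase, 11.7-fold lower, with Snap25 2.51-fold and Rbfox3 2.72-fold lower. Nqo1 was 2.42-fold higher (log2 1.28, SE 0.19, adjusted p = 0.000428), Txnrd1 1.67-fold and Cybb 2.76-fold. Gfap and Col1a1 did not pass (log2 0.44 and 0.20, adjusted p 0.156 and 0.638), nor did Cat and Slc7a11 (-0.24 and -0.33, adjusted p 0.196 and 0.4). In all, 5525 genes passed, 2885 higher and 2640 lower (edgeR). Of these, 2410 higher and 2123 lower genes were shared with SCI_Veh against sham, where independent lists would share 561.8 and 489. The correlation of both sets of log2 changes across genes, which are not independent replicates, was 0.892, against 0.5003 in simulations of shared sham libraries without other change.

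Against sham, camera called 21 lists for SCI_ALA, 15 higher and 6 lower, and 4 with an estimated correlation. Reactive astrocyte genes were higher in 14 of 15 (14 adjusted over the list alone, median 2.41, the same with Serpina3n at its bound), with an adjusted p of 0.00303 by that estimate. Phagocytic macrophage genes were higher in 15 of 17 (16 adjusted over the list alone, median 2.35, 0.0243), and cell cycle genes in 16 of 16 (16 adjusted over the list alone, median 2.91, 0.0207). Apoptosis genes were higher in 10 of 12 (10 adjusted over the list alone, median 1.19, 0.0349). NRF2 targets rose in 10 and fell in 1 of 16 (11 and 1 adjusted over the list alone, median 0.64, adjusted p = 4.62e-05). They had adjusted p = 0.118 with an estimated correlation (lowest over the alternatives 8.85e-07). Cholesterol synthesis genes fell in 16 of 16 (16 adjusted over the list alone, median -2.10, adjusted p = 1.17e-26), and had adjusted p = 0.0656 with an estimated correlation (lowest over the alternatives 9.03e-37). Also called higher were alternatively activated macrophage, cytokine, inflammasome, complement, NADPH oxidase, stress response and immediate-early genes (medians 2.13, 2.55, 1.12, 1.40, 1.84, 0.56 and 1.32). Higher members numbered 7, 11, 10, 7, 8, 5 and 6, and 7, 13, 10, 7, 8, 6 and 7 adjusted over the list alone. With an estimated correlation these lists had adjusted p = 0.074, 0.233, 0.233, 0.233, 0.0998, 0.118 and 0.131 (lowest over the alternatives 4.96e-10, 1.36e-08, 1.41e-06, 4.28e-09, 1.16e-08, 2.65e-05 and 2.81e-05). Called lower were presynaptic, neurotransmitter, myelin, homeostatic astrocyte and interferon-stimulated genes (medians -1.12, -1.42, -1.47, -1.65 and -1.45). Lower members numbered 10, 12, 11, 13 and 8, and 11, 14, 13, 13 and 9 adjusted over the list alone. Their adjusted p = 0.289, 0.237, 0.233, 0.0713 and 0.35 with an estimated correlation (lowest over the alternatives 9.35e-06, 2.21e-09, 2.28e-12, 6.48e-15 and 1.49e-10).

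In the same comparison 3 called lists lost their call without single libraries. Lymphocyte markers rose in 7 of 9 (8 adjusted over the list alone, median 2.11, adjusted p = 0.0142), with 0.0576, 0.102, 0.0509 and 0.0795 without SCI_Veh 2 and SCI_ALA 1, 2 and 3. Glycolysis genes had 8 higher and 2 lower of 15 (9 and 2 adjusted over the list alone, median 0.49, adjusted p = 0.0224), with 0.0526 without sham 3 and 0.0509 without SCI_ALA 2. Ferroptosis genes had 5 higher and 2 lower of 14, the same adjusted over the list alone (median 0.49, adjusted p = 0.0398), with 0.0509 without SCI_ALA 2. These 3 lists had adjusted p = 0.244, 0.392 and 0.289 with an estimated correlation (lowest over the alternatives 0.00314, 0.0027 and 0.00257). Other lists passed when single libraries were left out. Extracellular matrix genes had 5 higher of 16 (5 adjusted over the list alone, median 0.24, adjusted p = 0.071), with 0.0449, 0.0286, 0.0403, 0.00612 and 0.0478 without SCI_Veh 1, 2 and 3, sham 3 and SCI_ALA 3 (range 0.00612 to 0.576). Antioxidant enzymes had 4 higher and 1 lower of 15, the same adjusted over the list alone (median 0.27, adjusted p = 0.0806), with 0.00574 without sham 2 and 0.0114 without SCI_ALA 1 (range 0.00574 to 0.611). Precursor markers had 1 higher and 3 lower of 9 (1 and 4 adjusted over the list alone, median -0.51, adjusted p = 0.081), with 0.0368 without sham 2 and 0.0278 without SCI_ALA 1 (range 0.0278 to 0.392). Motor neuron markers had 1 higher and 4 lower of 7, the same adjusted over the list alone (median -1.02, mean -0.69, adjusted p = 0.139), with 0.0463 without sham 1 (range 0.0414 to 0.437).

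Medians of the other lists against sham were 0.48 for homeostatic microglia, 0.38 for neutrophil, 0.43 for erythroid, 0.63 for muscle and -0.70 for Schwann cell markers (adjusted p 0.427, 0.427, 0.726, 0.569 and 0.165). They were -0.33 for lipoic acid, -0.17 for respiratory chain, -0.21 for MHC class II and 0.08 for endothelial genes, the last with a mean of -0.25 and the test pointing down (adjusted p 0.161, 0.3, 0.78 and 0.49). In these lists 3, 1, 0, 0, 1, 1, 1, 0 and 1 members were higher and 2, 0, 0, 0, 3, 3, 3, 0 and 3 lower by edgeR. Adjusted over the list alone, the counts were the same but for 4 microglia markers higher and 4 Schwann cell markers lower. The muscle and erythroid lists also had 0 genes at an unadjusted p and by DESeq2, and the MHC class II list 1. Chat was 2.36-fold lower (adjusted p = 0.0192), with 0.0829, 0.0542 and 0.0779 without sham 3, SCI_ALA 1 and SCI_ALA 3 (range 0.00404 to 0.0829). Il6 was 7.85-fold higher (0.0233), with 0.0519 without sham 1 and 0.151 without SCI_ALA 2 (range 0.00302 to 0.151). Nlrp3 was 2.17-fold higher (0.0196), with 0.06, 0.0599, 0.0989 and 0.0537 without sham 2, sham 3, SCI_ALA 2 and SCI_ALA 3 (range 0.00422 to 0.129).

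Further fixed genes did not pass against sham but did without 1 library. Mbp had a log2 change of -0.82 (adjusted p = 0.0507), with 0.0185 without sham 3 and 0.0414 without SCI_ALA 3 (range 0.00723 to 0.174). P2ry12 had 0.50 (0.0775), with 0.0462 without SCI_ALA 2 (range 0.0462 to 0.362). Sod1 and Sod2, superoxide dismutases, had 0.47 and 0.69 (0.0617 and 0.1). Sod1 had 0.00727 without sham 2 and 0.0369 without SCI_ALA 1 (range 0.00727 to 0.33), and Sod2 0.0226 without SCI_ALA 1 (range 0.0226 to 0.556). Gclm had 0.31 (0.0908), with 0.0452 without sham 2 (range 0.0444 to 0.234), and Dld -0.39 (0.0773), with 0.0215 without sham 1 (range 0.0215 to 0.21). Il1b had 2.55 (0.0824), with 0.0195 without SCI_ALA 1 and 0.0447 without SCI_Veh 3 (range 0.0195 to 0.327).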

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

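Removal of the length trend and leaving out sham 2 and SCI_ALA 3 together were tests chosen after the result was seen; the other alternatives were fixed before. No named gene that passed and no called list reversed its direction. Among lists without a call between the injured groups, the median of the apoptosis genes went from 0.03 to -0.03 with library totals only and that of the antioxidant enzymes from 0.10 to -0.05 with the length trend removed. Where a result moved or changed sign the cause was not tested, apart from those that test fewer genes or libraries by construction. For SCI_Veh against sham and SCI_ALA against sham, 23 of 24 alternatives stayed within 1.5 times the count of 6337 and 5525 genes (without single libraries 4773 to 6225 and 3895 to 5676), and 22 of 23 for the 6133 genes that differed among the 3 groups (5141 to 6010). A minimum log2 fold change of 1 gave 3801, 3257 and 4053. For SCI_ALA against SCI_Veh, 6 of 24 alternatives stayed within 1.5 times the 20 genes. The count was 1 with library totals only, 45 without a count filter, 1 with robust=FALSE, 161 with only the 2 groups compared, 416 with DESeq2, and 3, 0 and 1 with limma on FPKM (pseudocount 1, pseudocount 0.1, and pseudocount 1 over all genes; 2030, 1945 and 2504 at an unadjusted p). Without single libraries it ran from 0 to 86. For the 15 genes moved back, 6 of 23 alternatives stayed within 1.5 times. The count was 1 with library totals only, 28 without a count filter, 1 with robust=FALSE, 255 with DESeq2, 2, 0 and 1 with limma on FPKM in the order above, and 0 to 51 without single libraries. It was not computed with only the 2 groups compared, since it needs both comparisons. Of lists, 22, 12 and 21 were called; a correlation estimated per list gave 4, 0 and 4 (for SCI_ALA against SCI_Veh, 12 with the preset correlation and 2 with fry), and the removal of the length trend gave 7 of the 12. Left-out libraries gave 20 to 25, 9 to 15 and 18 to 23. Named genes kept their call in every alternative for 136 of 152 in SCI_Veh against sham, 0 of 19 in SCI_ALA against SCI_Veh and 17 of 21 in SCI_ALA against sham (edgeR and DESeq2).

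With the replicate number as a replicate block, 6216, 0 and 5363 genes passed in the order above (2096 at an unadjusted p for SCI_ALA against SCI_Veh, edgeR), 5926 differed among the groups, 0 genes moved back, and 22, 12 and 24 lists were called. Correlations of the libraries' deviations from their group means gave no clear sign of pairing by number, which this check cannot exclude. Of 18 best matches 9 had the same number, and 2 of 9 same-number correlations exceeded 0.1 (-0.0855 to 0.18). The highest of these were among the replicate 1 libraries (0.0954, 0.134 and 0.18), while sham 2 and SCI_ALA 3, of unlike number, had 0.166. The share of hemoglobin genes, however, rose with the replicate number in every group. It was 0.0373, 0.0755 and 0.177% in sham, 0.0497, 0.0560 and 0.155% in SCI_Veh and 0.0902, 0.158 and 0.270% in SCI_ALA. What libraries of equal number have in common was not tested. At this depth and number of libraries, 23.9% to 31.3% of simulated 2-fold changes and 69.7% to 80.3% of 4-fold changes were recovered. Few genes were changed in these simulations, and depth itself was not varied.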

Other observations

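Tests chosen only after the result was seen were those of the gene families, of the length trend in lists, of the share of injured tissue, of gene copies and of the shared libraries; the counts of splits were fixed before. The length trend was chosen for removal after seeing the data, and its test of the covariance before that value was seen.

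Gene families chosen after seeing the data added to the picture of injury. Cathepsins, lysosomal proteases, rose in 9 of 13 genes in SCI_Veh against sham (median log2 1.35; camera adjusted p = 3.68e-09; adjusted p = 0.309 with an estimated correlation), with Ctsd 8.89-fold and Ctsb 6.71-fold higher, and annexins rose in 7 of 10 (median 0.83; adjusted p = 0.0023; adjusted p = 0.309 with an estimated correlation), with Anxa2 4.01-fold higher. S100 proteins split: S100a11 was 6.70-fold higher and S100b, made by astrocytes, 3.97-fold lower (median -0.14 while the test pointed up; adjusted p = 0.114). Potassium channel subunits fell in 35 and rose in 4 of 72 (median -1.10; adjusted p = 3.21e-06; adjusted p = 0.309 with an estimated correlation): Kcnj11 was 5.61-fold lower and Kcnn4, a calcium-activated channel of immune cells, 13.6-fold higher. Scn1a, a neuronal sodium channel gene, was 8.27-fold lower.

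Between the injured groups, the 4 metallothioneins, metal-binding proteins, had a median of 1.29 (0 passed by edgeR; adjusted p = 4.52e-05; adjusted p = 0.398 with an estimated correlation; median 1.03 with the length trend removed). The 84 cytosolic ribosomal protein genes had a median of 0.47 (1 higher and 1 lower, camera adjusted p = 6.93e-13, and 0.793 with an estimated correlation, median 0.29 with the trend removed). The 13 cathepsins had a median of -0.24 (camera adjusted p = 0.0223, and 0.793 with an estimated correlation). Camera also called 12 S100 proteins higher (median 0.438, adjusted p = 0.00336, and 0.793 with an estimated correlation, median 0.238 with the trend removed). So were 38 proteasome subunits (median 0.125, adjusted p = 0.00999, and 0.809 with an estimated correlation, median 0.0671 with the trend removed).

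Of 100 splits of the 9 libraries into 3 groups, drawn from 280, 1, the real one, gave as many as 6133 genes. A random grouping of these libraries is thus an unlikely source of that count. Replicates may not be separate animals, so chance differences between animals are not excluded. The highest other split gave 5288. A further look at the 5 other splits that kept the sham libraries together gave 4668 or more, so the split of sham from injury carries the count. For pairs of groups, 10 splits are too few for a share under 0.05. Real and highest other counts were 6337 and 0 genes (1 split as large, counting the real one) and 22 and 22 lists (2 splits) for SCI_Veh against sham. They were 20 and 1 genes (1 split) and 12 and 20 lists (4 splits) for SCI_ALA against SCI_Veh, 5525 and 3 genes (1 split) and 21 and 23 lists (4 splits) for SCI_ALA against sham, and 15 and 0 genes moved back (1 split). Under the rule fixed beforehand, at least 1 other split with as many lists was what chance would give. In the order above, 1, 3 and 3 other splits had as many, and every other split called at least 11, 7 and 11 lists. The number of called lists therefore does not set the real groups apart from other splits.

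Precursor, microglia, macrophage and cell cycle lists were lower in SCI_ALA than in SCI_Veh by camera, but with an estimated correlation they had adjusted p = 0.166, 0.186, 0.231 and 0.64, and by fry the macrophage and cell cycle lists had 0.0649 and 0.274. With the length trend of each library removed, 4 of these 4 lists kept their call. Precursor and cell cycle genes were longer than the tested genes as a whole (median lengths 3925 and 2924.5 against 2240). For these lists the kept call argues against gene length bias as the whole cause. Microglia and macrophage genes were shorter (1471.5 and 1698), and the tilt of SCI_ALA toward short genes would raise them. Their kept call was therefore no test of that bias. A smaller share of injured tissue in the SCI_ALA samples would lower reactive astrocyte genes along with macrophage genes. Their means were 0.14 and -0.54 (weighted fry p of the difference = 0.0284), which argues against a smaller share as the whole cause for the macrophage list. A part stays open, since 7 of 15 lists raised by injury had a median below 0 and 8 above, and of the 7 lists lowered by injury 4 had a median above 0 in SCI_ALA against SCI_Veh (presynaptic 0.33, neurotransmitter 0.42, respiratory chain 0.22 and homeostatic astrocyte 0.17) and 3 below (cholesterol synthesis -0.30, myelin -0.18 and interferon -0.06). The precursor list was not raised by injury (median 0.196, camera adjusted p = 0.459). A smaller share alone would not place it below sham, but SCI_ALA against sham did not pass (median -0.512, camera adjusted p = 0.081). An effect of α-lipoic acid on the cells of these 4 lists was not tested apart from these alternatives and stays open. So does a difference in the sampled part of the lesion that affects these cell types alone. The alternatively activated macrophage list had a median of 0.46 in the same comparison (adjusted p = 0.0783). For the higher respiratory chain, erythroid, neutrophil and muscle lists and the lower matrix list, 0 of 5 kept their call with the trend removed (medians from 0.22, 1.04, 1.49, 0.70 and -0.43 to 0.15, 0.87, 1.24, 0.62 and -0.37; SD over members 0.192, 0.122, 0.73, 0.56 and 0.511), so length bias is a candidate explanation of part of those calls, which ended on small shifts. Within SCI_ALA, erythroid, neutrophil and respiratory chain levels rose with the tilt toward short genes from library 1 to 3 (4.07, 5.01 and 5.76, then 2.89, 4.66 and 4.89, then 7.82, 8.04 and 8.15), and within sham the respiratory chain level was highest in sham 2 (8.58). Other levels did not follow the tilt. Erythroid levels also rose from library 1 to 3 in SCI_Veh (3.149, 3.245 and 5.038) and in sham (3.63, 4.073 and 5.772). Neutrophil levels were highest in library 3 of every group. The tilt did not run in that order in SCI_Veh or sham. For these 2 lists, the tilt within SCI_ALA cannot be told apart from an order by replicate number. Neutrophil and erythroid levels were highest in sham 3 (5.08 and 5.77), the library most favouring long genes, and the muscle level was 0.69 in SCI_ALA 3, the library most favouring short genes, below 1.37 in SCI_Veh 1.

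Rplp2 was lower in SCI_ALA, but the 5 genes described as the same protein summed to a log2 change of 0.0707. The most abundant copy, LOC498555, had a log2 change of 0.491, near the median of 0.47 over the 84 ribosomal protein genes. A sum near 0 could come from reads that moved between copies. It could also come from a real fall of Rplp2 beside such a rise, and the sum cannot tell these apart. For Rps27a, the copy on chromosome 14 had a log2 change of 1.69 and the copy on chromosome 5 of -0.96, while 3 summed copies changed by 0.548. Reads shared between copies and a real rise cannot be told apart, since the sum lies between the values that either would give. Those values made no allowance for the family median of 0.47, near which this sum lies.

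Changes under α-lipoic acid ran opposite to those of injury more often than the shared SCI_Veh libraries alone gave in simulations (covariance -0.246, simulated -0.119 to -0.0861). For the 20 arrangements of the injured libraries the covariance was computed from differences of mean log2 CPM instead of fitted changes, so it is not comparable with the simulated range. The real one was lowest (-0.206, with the lowest other at -0.188 and an SD of 0.0636), but by less than that SD, and by correlation 3 others were more negative (the lowest -0.413, the real one -0.367), so the shared libraries and a partial return toward sham cannot be told apart. With the length trend removed the covariance was -0.254, outside the simulated range. The simulations drew each gene independently and held no length trend of single libraries or between the injured groups, so that range may be too narrow to judge by. The covariance did not shrink from -0.246 when the trend was removed, but this was a weak test of gene length bias. Log2 changes had Spearman correlations with gene length of -0.031 in SCI_Veh against sham and -0.277 in SCI_ALA against SCI_Veh. Trends of equal sign would not make the covariance negative, so their removal could hardly shrink it. A partial return may be tested with vehicle libraries held apart for each comparison.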
